A study of Mus musculus with 144 samples.

How the data were processed

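The samples were EpiSC-5 mouse epiblast stem cells in CMAF at 0 h and under 5 treatments at 8 times, 144 libraries in 41 groups. Groups were read from the treatment, time and replicate number in each title. Per the labels' protocols, poly-A RNA was made into libraries with a TruSeq kit and sequenced as single-end reads on HiSeq instruments of 2 models. The labels do not say which library was run on which model, so it could not be used as a batch. Per the submitters' processing notes, reads were aligned with TopHat 1.3.3 to mm9, and DESeq was named. The counter, the annotation and any use of strand are not given in the sources used here. Each library's file gave an Entrez Gene ID and a whole-number count, taken as raw counts per gene as deposited. Coordinates are not given, since no annotation of that build was at hand.

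Symbols came from a RefSeq table of assembly GRCm38.p6, used for names only, which matched 23185 of the 23283 IDs. The 11 genes named throughout were Pou5f1 (Entrez Gene 18999), Nanog (71950), Sox2 (20674), Sox1 (20664), T (20997), Sox17 (20671), Foxa2 (15376), Cyp26a1 (13082), Id1 (15901), Lefty2 (320202) and Axin2 (12006). There were 1976 genes with 0 counts in all libraries. Among expressed genes, 42 shared identical counts in every library with another gene, and overlapping genes cannot be told apart. RA 72 h replicate 6 was left out because it held 80604 counts in 76 genes, and 75 of the 75 with a known position lay on chromosome 1, as if the file stopped early. The 143 libraries used held between 4965716 and 16396596 counts. Intervals and floors cover counting error only.

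Changes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), using the quasi-likelihood test with robust fitting on the deposited counts. TMM scaling gave factors of 0.744 to 1.07, and filterByExpr by group left 16048 genes. All groups entered one fit without covariates, and every p for a gene is adjusted by the Benjamini-Hochberg method over all genes tested in its comparison. A gene was called changed at an adjusted p under 0.05 with a log2 fold change of at least 1 either way. Each treatment was compared with CMAF at 6, 24 and 72 h and at the times with 2 libraries. RA was also compared with BMP4 at 72 h, WAFB with WA at 24 and 72 h, and SB with RA at 72 h. RA at 3 h and WA at 48 h, with 1 library each, were not tested. Values are means of CPM, counts scaled to library size, with the SD between libraries. Log2 changes come with a standard error (SE) worked back from the change and the F statistic of its test. Against 0 counts in a group, a lower bound on the fold was taken from a floor of 3 counts over the group. No fold is given where a group had fewer than 10 counts in sum.

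The comparisons, their tests and the alternatives were chosen before the data were examined, as were 30 gene lists of 393 genes in all. The lists covered naive and primed pluripotency, targets of the Activin and Nodal, Wnt, BMP, FGF and ERK, retinoic acid and p53 pathways, Hox paralogues 1 to 5 and 6 to 13, primitive streak, definitive and extraembryonic endoderm, paraxial, lateral plate and cardiac, and extraembryonic mesoderm, blood and endothelium, neural plate, neurons, hindbrain and spinal cord, neural crest, surface ectoderm, trophoblast, germ cells, mesenchymal genes, fibroblasts, the integrated stress response, cholesterol synthesis, glycolysis and hypoxia, and the cell cycle. Each list was tested with camera, with a preset correlation of 0.01 and with an estimated one, and its p adjusted over the 30 lists of a comparison.

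Genes were named by a rule also fixed beforehand. At 72 h these were the 6 largest rises and 6 largest falls among changed genes with at least 10 counts in each group, at least 5 CPM in the higher group and every treated library beyond every control library. From each list with 3 or more changed members, up to 3 changed members were named, and the first 3 members of the 6 signalling lists could be named in any case. At 6 and 24 h they were the 3 largest each way and changed signalling targets. Between treatments they were the 6 largest each way and up to 3 differing members per list. The 11 genes given above could be named anywhere. Genes outside the rule are said to be chosen after their values were seen. Some genes that met the rule are not reported here.

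The test was tested on simulated data with known changes in 200 genes. These were drawn only from genes well above 0 counts per library in CMAF, and counts were simulated with the spread estimated from the data. The shares recovered do not cover genes near 0 counts in CMAF, nor comparisons in which many more genes change. In the layout of RA at 72 h against CMAF (5 against 6 libraries, 13922 genes), 86% of 1.5-fold, 88% of 2-fold and 100% of 4-fold and 8-fold changes had an adjusted p under 0.05. Of 13722 unchanged genes 5 did, and 1 was called changed. The fold threshold lowered the calls at 2-fold to 44%. In the layout of BMP4 at 12 h (2 against 6), the adjusted p found 72% of 1.5-fold, 80% of 2-fold, 100% of 4-fold and 98% of 8-fold changes, and 2 unchanged genes were called.

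Alternatives were DESeq2 1.42.0, median-ratio (RLE) scaling, no filter on low counts, only the groups compared, a replicate block, subsets of replicates, leaving out 1 replicate number of the treated groups or 1 CMAF library, and an estimated correlation for the lists. Overlaps between treatments were set beside independent lists, simulated unchanged groups and controls split in 2 parts, each 20 times. Other splits of the libraries were drawn 60 times per comparison out of 462. Samples far from their group were found with Dixon's test. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.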

Results

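Poly-A RNA was sequenced from EpiSC-5 cells, a mouse epiblast stem cell line. Such cells resemble the epiblast after implantation and stay pluripotent in conditioned medium with bFGF and Activin A, a mixture called CMAF here. Cells in CMAF at 0 h were compared with cells given 5 other media for up to 72 h. RA was 5 µM retinoic acid in conditioned medium without bFGF or Activin A. BMP4 was 100 ng/ml of that factor in conditioned medium. SB was SB431542, an inhibitor of the Activin and Nodal receptors, labelled as 10 nM, a unit that could not be checked here, in serum-free medium. WA, which the labels call endoderm differentiation, was Wnt3a and Activin A with 0.075 mM EGTA in RPMI for 24 h. It was then Activin A with 0.2% FBS for 48 h. WAFB, which they call mesoderm differentiation, was Wnt3a and Activin A, with FGF2 added on the second day and BMP4 on the third.

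The 144 libraries formed 41 groups. There were 6 libraries per group at 0, 6, 24 and 72 h and 2 at 3, 12, 18, 36 and 48 h, except for a single library each of RA at 3 h and WA at 48 h. RA 72 h replicate 6 held only 80604 counts in 76 genes, all 75 with a known position on chromosome 1, and was left out, so RA 72 h had n = 5. The other 143 libraries held between 4965716 and 16396596 counts and 15720 to 17490 detected genes. The labels do not say whether replicates were separate cultures, so the spread between them may be technical only. CMAF was sampled at 0 h alone. A difference from CMAF therefore joins the named factors with the change of medium, the handling and the time in culture.

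CMAF cells carried the transcripts of the primed epiblast. Pou5f1 stood at 1660 ± 47 CPM (SD, n = 6), Sox2 at 92.1 ± 4.43, Nanog at 60.9 ± 7.15, Dnmt3b at 3620 ± 125, Fgf5 at 127 ± 9.36 and Lefty1 at 140 ± 9.52. Some lineage genes and the BMP target Id1 were close to background: Sox1 at 0.66 ± 0.301 CPM, T at 0.402 ± 0.273, Foxa2 at 0.263 ± 0.358 and Id1 at 1.12 ± 0.226. Other members of the lineage lists were expressed, such as Trh (definitive endoderm) at 636 ± 15 CPM, Otx2 (neural plate) at 108 ± 6.76 and Foxd3 (neural crest) at 58.7 ± 8.45. Sox17 and Cyp26a1 had 3 counts each over the 6 CMAF libraries. Of 16048 genes tested, 921 (BMP4) to 1956 (WA) changed at 6 h, 2161 (SB) to 3384 (RA) at 24 h and 4434 (WAFB) to 6326 (BMP4) at 72 h. A changed gene had an adjusted p under 0.05 and at least a 2-fold difference. At the adjusted p alone, 5459 (BMP4 6 h) to 12833 (BMP4 72 h) genes passed.

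**Figure D1:**
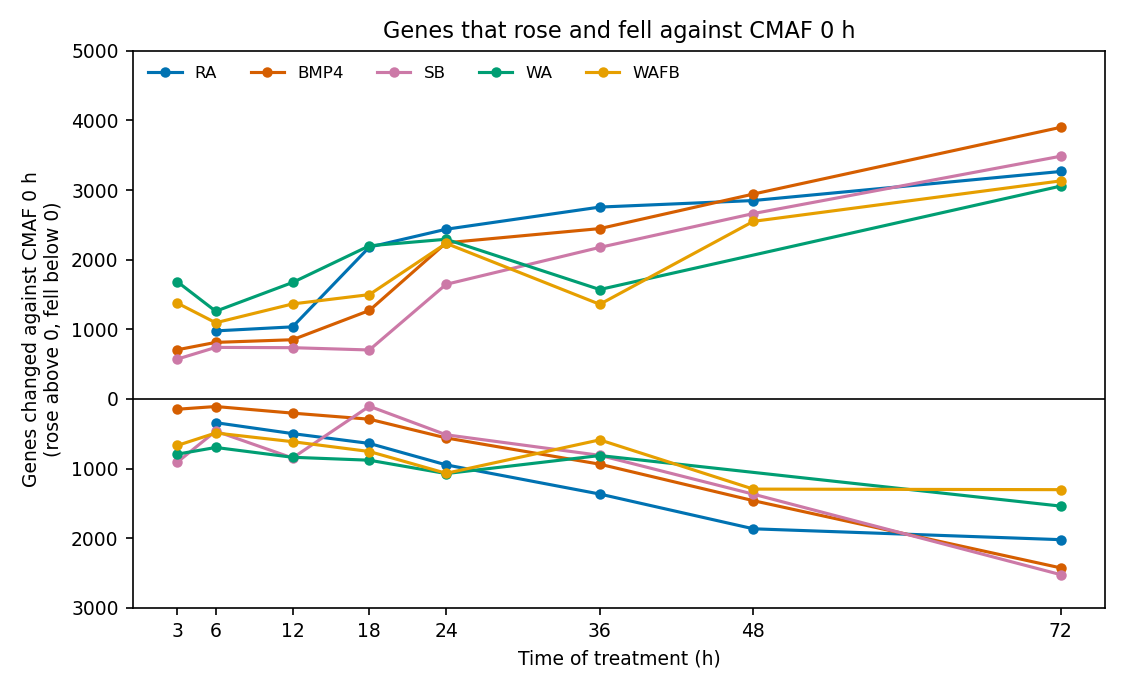
Number of genes that rose (above 0) and fell (below 0) against CMAF 0 h, on a linear axis, by hours of treatment; each point is 1 comparison. At 72 h the number that rose lay between 3056 (WA) and 3900 (BMP4); the SB value at 18 h includes a library that lay close to CMAF.

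In the list counts that follow, the count adjusted over the list alone equalled the count over all genes tested unless both are given. Where a camera p under 0.05 was lost with an estimated correlation between genes, the second value is given. Folds and CPM of the genes named come with every treated library beyond every CMAF library where they are among the largest changes.

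Retinoic acid was added to ask how epiblast cells respond to a signal that patterns the hindbrain and spinal cord. Within 6 h its own feedback genes and the anterior Hox genes came on. Cyp26a1, whose product clears retinoic acid, reached 287 ± 9.96 CPM (SD, n = 6). Meis2, a Hox cofactor, rose 256-fold (adjusted p = 1.8e-36). Of the 16 retinoic acid targets measured, 15 rose at 6 h (camera adjusted p = 2.22e-23), 14 at 24 h and 13 at 72 h. Of 15 Hox genes of paralogues 1 to 5, 12 rose at 6 h (14 adjusted over the list alone; adjusted p = 2.48e-12) and all 15 at 24 and 72 h.

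Activin and Nodal targets went down at the same time, in a medium without added Activin A: 7 of 10 fell at 6 h and none rose (adjusted p = 5.91e-05; adjusted p = 0.0895 with an estimated correlation). At 6 h Lefty2 was 18.1-fold lower, Nanog 15.5-fold, Lefty1 9.75-fold and Tdgf1 7.94-fold, while Pou5f1 was at 1480 ± 54.6 CPM and not called. At 24 h Pou5f1 was 7.15-fold lower and Nanog 15-fold, and the neural plate gene Sox1 was 175-fold higher at 124 ± 12.6 CPM. Zfp703 rose 576-fold and Crabp2 119-fold at 24 h. Sox2 was 2-fold higher at 24 h and lay 0.76 above CMAF on the log2 scale at 72 h, under the fold threshold. Changed genes numbered 977 up and 341 down at 6 h, and 2437 up and 947 down at 24 h.

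At 72 h neural, Hox and mesenchymal genes had risen in the RA cells and Pou5f1 had fallen. Of 11 mesenchymal genes 10 rose (adjusted p = 1.15e-05). Hoxd3 stood at 682 ± 33.1 CPM (SD, n = 5) and Hoxa3 at 431 ± 16.1, each from 1 count over the CMAF libraries. Genes with 0 counts in CMAF appeared, among them Dbx1 (57.4 ± 1.99 CPM, at least 773-fold higher), Pax3 (at least 604-fold) and Zic1 (at least 570-fold), and Neurog1 was at least 282-fold higher. Meis2 rose 623-fold (log2 9.28 ± 0.37 SE, adjusted p = 2.6e-45), Tshz1 357-fold, Dach1 334-fold, Pou3f2 239-fold and Irx3 115-fold. Pou5f1 was 370-fold lower (4.64 ± 3.78 CPM; log2 -8.53 ± 0.19 SE, adjusted p = 9.6e-69), Trh 359-fold, Utf1 309-fold, Lefty1 275-fold, Otx2 264-fold and Nanog 94.9-fold. Of 14 neural plate genes 10 rose and 1 fell (adjusted p = 0.00111), and of 13 neuronal genes 9 rose and 2 fell (adjusted p = 0.00517; adjusted p = 0.108 with an estimated correlation). Of 12 hindbrain and spinal cord genes 7 rose and none fell (adjusted p = 0.0104; adjusted p = 0.0601 with an estimated correlation), and of 11 neural crest genes 8 rose and 1 fell (adjusted p = 0.00548). All 10 Activin and Nodal targets fell (adjusted p = 6.75e-05; adjusted p = 0.0679 with an estimated correlation). Of 16 FGF and ERK targets 9 fell and 3 rose (adjusted p = 0.00369; adjusted p = 0.0989 with an estimated correlation), with Spry4 37.7-fold, Etv5 31.9-fold and Etv4 28.9-fold lower. In all, 3266 genes rose and 2021 fell.

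BMP4 was tested as a signal for ventral and extraembryonic mesoderm, amnion and surface ectoderm. Id1, a target of the BMP pathway, was at 226 ± 15.1 CPM (SD, n = 2) at 3 h, 236 ± 13.5 (n = 6) at 24 h and 186 ± 18.6 (n = 6) at 72 h. At 6 h Id1 was 154-fold higher (log2 7.27 ± 0.21 SE, adjusted p = 1e-54), Id4 16.7-fold, Id3 10.5-fold, Msx1 10.5-fold and Smad6 4.16-fold. Of 14 BMP targets 12 rose at 6 h (adjusted p = 2.92e-25) and 13 at 24 h (adjusted p = 7.05e-15). At 6 h Nanog was 2.31-fold lower, and Lefty1, at 140 CPM in CMAF, was at 83.7 CPM in replicate 6, which lay between CMAF and its group, and at 1.19 ± 0.377 (n = 5) in the others. By 24 h Tfap2a had risen 142-fold, Gata3 had reached 35.6 ± 2.13 CPM and Msx2 65.8 CPM. Fgf5 had fallen 58.2-fold. Pou5f1 (957 ± 60.2 CPM) was 1.74-fold lower (adjusted p = 1e-09), under the fold threshold, and Nanog (75.4 CPM, adjusted p = 0.057) was not called. Changed genes numbered 812 up and 109 down at 6 h. In a fit without replicate 6 of every treated group of 6 libraries, the total at 6 h was 1053 rather than 921. At 24 h 2242 rose and 560 fell.

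By 72 h the BMP4 cells expressed genes of lateral plate, cardiac and extraembryonic mesoderm together with surface ectoderm and trophoblast genes. Igf2 rose 1550-fold to 8560 ± 273 CPM (SD, n = 6; log2 10.60 ± 0.30 SE). Hand1, which marks lateral and extraembryonic mesoderm, reached 584 ± 23 CPM, Msx2 244 ± 15.5 and Tbx3 145. Pmp22 rose 1020-fold, Dlk1 609-fold, Smoc2 452-fold, Col1a1 382-fold and Pdgfrb 217-fold. All 14 lateral plate and cardiac genes rose (adjusted p = 8.05e-07), as did 10 of 11 blood and endothelium genes (adjusted p = 0.00777), all 11 extraembryonic mesoderm genes (adjusted p = 2.14e-06), 14 of 15 surface ectoderm genes (adjusted p = 1.39e-07) and 9 of 11 trophoblast genes (adjusted p = 0.000312). Hox genes were called higher along the series, with all 15 of paralogues 1 to 5 (adjusted p = 7.41e-06) and 14 of 15 of paralogues 6 to 13 (adjusted p = 4.03e-05; adjusted p = 0.0701 with an estimated correlation). Some stayed near background, with Hoxa4 at 0.145 CPM (9 counts) and Hoxa5 at 0.346 CPM (20 counts), while Hoxd9 was at 11.1 CPM. Of the retinoic acid targets 13 rose (adjusted p = 5.12e-05). Foxd3 was 225-fold lower, Fgf5 164-fold, Pou5f1 25.7-fold (64.7 ± 5.71 CPM), Nanog 18.4-fold and Sox2 11.3-fold. Neural plate genes went down, with 5 of 14 lower and 1 higher (adjusted p = 0.041; adjusted p = 0.108 with an estimated correlation). In all, 3900 genes rose and 2426 fell.

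SB431542 blocks the receptors that Activin A and Nodal signal through, and SB cells also left conditioned medium with bFGF and Activin A, so the comparison joins these changes. Activin and Nodal targets fell within 6 h. Lefty1 was 421-fold lower (0.313 ± 0.232 CPM, n = 6), Nanog 74.9-fold, Smad7 48-fold, Lefty2 37.6-fold, Pmepa1 34.9-fold and Nodal 23.9-fold. Of 10 Activin and Nodal targets 8 fell at 6 h (adjusted p = 6.74e-12) and 8 at 24 h (adjusted p = 1.28e-10), and none rose. Of 12 primitive streak genes 5 fell at 6 h (adjusted p = 0.00134; adjusted p = 0.0785 with an estimated correlation). Pou5f1 lasted longer, at 1480 ± 104 CPM at 6 h and 635 ± 53.1 at 24 h. At 24 h Tdgf1 was 736-fold lower, Dusp4 was 19.3-fold higher and Fos 64.7-fold higher, and Sox1 had risen 6.88-fold. Genes that rose and fell numbered 740 and 462 at 6 h, and 1646 and 515 at 24 h.

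At 72 h the SB cells had raised surface ectoderm genes and p53 targets. The cardiac myosin gene Myh7 rose 3940-fold to 1130 ± 85.7 CPM (SD, n = 6; log2 11.94 ± 0.29 SE, adjusted p = 4.5e-75). Cryab rose 900-fold, Myh6 633-fold, Csf1 512-fold, Anxa2 399-fold, Krt19 268-fold and Col4a2 219-fold. Of 14 lateral plate and cardiac genes 8 rose and none fell (adjusted p = 0.106). Targets of p53 rose, 11 of 13 (adjusted p = 4.97e-07), with Perp 40.4-fold and Cdkn1a 9.84-fold higher, and 11 of 17 cholesterol synthesis genes fell (adjusted p = 5.31e-08), with Insig1 4.65-fold lower. Of 15 surface ectoderm genes 12 rose (adjusted p = 9.9e-06), and of 16 glycolysis and hypoxia genes 7 rose (adjusted p = 0.00676; adjusted p = 0.259 with an estimated correlation). Id1, at its CMAF level until 12 h, climbed to 167 ± 29.7 CPM, 148-fold above CMAF, in a medium with no added BMP4. Axin2 rose 13.8-fold. Sox1 was 8.15-fold higher, and 8 of 14 neural plate genes rose while 2 fell (adjusted p = 0.469). Pou5f1 was 210-fold lower (7.91 ± 1.92 CPM), and Lefty1 was at 0.17 ± 0.233 CPM (10 counts), Tdgf1 at 0.668 ± 0.835 and Nanog at 0.252 ± 0.313, whereas Sox2 changed by -0.22 on the log2 scale and was not called. In all, 3485 genes rose and 2523 fell.

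WA, the endoderm protocol, produced primitive streak transcripts first. T rose 114-fold at 6 h (49.5 ± 4.44 CPM, n = 6; log2 6.83 ± 0.25 SE, adjusted p = 8.1e-55), Axin2 10.6-fold, Lefty2 5.77-fold and Nanog 3.87-fold. Foxa2 rose to 11.9 ± 1.71 CPM from 13 counts over the CMAF libraries, which stood at 0.948 CPM in replicate 3 and 0 to 0.333 in the others, so no fold is given. Of 12 streak genes 10 rose (adjusted p = 5.99e-09), and of 14 Wnt targets 8 rose (9 adjusted over the list alone; adjusted p = 7.16e-05). Gbp2 was 228-fold and Irgm1 67.1-fold higher. Cholesterol synthesis genes went down at 6 h, 3 of 17 past the fold threshold (adjusted p = 1.74e-13). By 24 h T was back at 0.463 ± 0.291 CPM (adjusted p = 0.76 against CMAF), while Foxa2 was at 3.55 ± 1.23 CPM and Nanog was still 2.61-fold above CMAF. Sox2 was 3.7-fold and Pou5f1 2.1-fold lower. At 6 h 1259 genes rose and 697 fell, and at 24 h 2293 rose and 1072 fell.

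At 72 h the WA cells again carried streak genes, with mixed changes in definitive endoderm genes. T was 33.4-fold higher (14.5 ± 2.42 CPM, n = 6), Lefty2 7.92-fold (188 ± 27.1 CPM) and Axin2 7.61-fold, and Sp5 was at 28.3 ± 2.08 CPM. Of 12 streak genes 10 rose (adjusted p = 0.000525). Of 13 definitive endoderm genes 9 rose and 2 fell (adjusted p = 0.118). Of these Krt19 was at 206 ± 70.4 CPM, Foxa2 at 2.72 and Sox17 at 1.28 ± 0.857 CPM, 64 counts against 3. Krt19 is also on the surface ectoderm list, and in RA at 72 h it was 63.3-fold above CMAF. Gbp2 was 883-fold higher, Cryab 472-fold, Acta1 299-fold, Anxa2 243-fold and Krt19 227-fold. Slc35d3 was 81.3-fold lower, Elavl3 62.2-fold, Dnmt3a 10.5-fold, Dnmt3b 9.75-fold and Pou5f1 3.31-fold (501 ± 47.3 CPM). Nanog, at 42.2 ± 6.11 CPM, was not called. In all, 3056 genes rose and 1539 fell. Replicate 4 lay apart from its group. A fit without it, which also left out libraries of other groups, gave 4516 rather than 4595 changed genes.

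WAFB, the mesoderm protocol, also began with streak transcripts. At 6 h T was 27.7-fold higher (12 ± 0.967 CPM, n = 6), Lefty2 4.48-fold and Axin2 3.03-fold, Foxa2 was at 3.23 ± 1.91 CPM, and 6 of 12 streak genes rose (adjusted p = 0.000924; adjusted p = 0.066 with an estimated correlation). At 24 h T was at 0.148 ± 0.131 CPM and not called (adjusted p = 0.077). T was back before BMP4 was added, and at 72 h it was at 68.3 ± 12.1 CPM, 157-fold above CMAF (log2 7.29 ± 0.24 SE, adjusted p = 2.7e-60), and Id1 at 204 ± 19.2 CPM, 181-fold. Hand1 was at 35.8 ± 8.66 CPM, Gata2 at 34.3, Evx1, a gene of the posterior streak, at 23 ± 4.63, and Igf2 was 133-fold higher. Of 14 BMP targets 13 rose (adjusted p = 4.88e-08), of 14 Wnt targets 10 (adjusted p = 0.000469), of 12 streak genes 9 (adjusted p = 0.000739), of 14 lateral plate and cardiac genes 9 (adjusted p = 0.00291) and of 11 trophoblast genes 10 (adjusted p = 2.78e-06). Targets of p53 rose as well, 10 of 13 (adjusted p = 3.12e-07). Slc35d3 was 81.5-fold lower, Trh 24-fold, Lefty1 8.43-fold, Nanog 3.6-fold and Pou5f1 2.35-fold (707 ± 73.1 CPM). Changed genes numbered 1094 up and 489 down at 6 h, 2234 and 1068 at 24 h, and 3131 and 1303 at 72 h. In a fit without replicate 4 of every treated group of 6 libraries, the total at 6 h was 1496 rather than 1583.

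**Figure D2:**
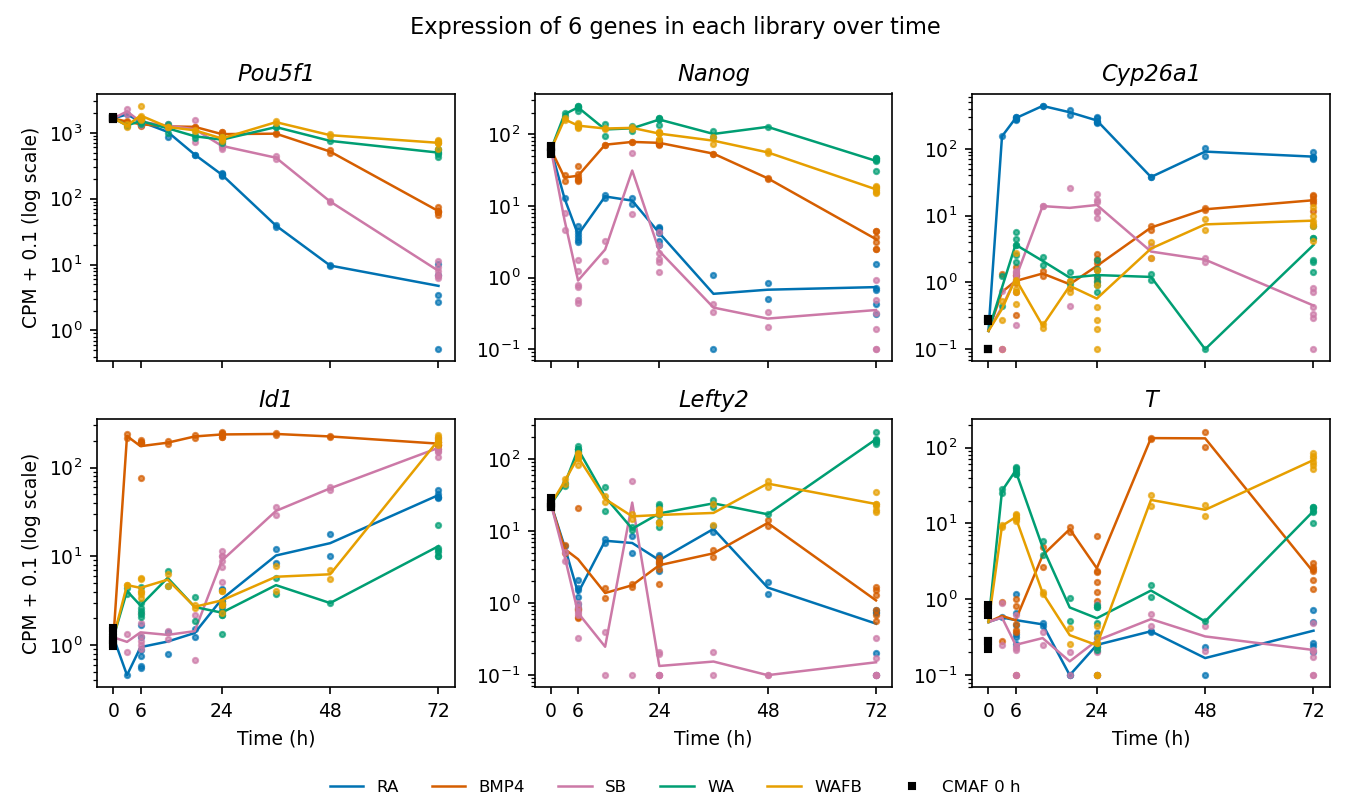
CPM plus an offset of 0.1 (log axis) of 6 genes by hours of treatment; points are libraries, squares the 6 CMAF libraries and lines group means. Id1 was at 226 CPM by 3 h in BMP4 and at 204 CPM at 72 h in WAFB, and T peaked at 36 and 48 h in BMP4; the 2 SB libraries at 18 h lay far apart.

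The times with 2 libraries showed when these programmes started, and their spread was borrowed from all groups. RA cells lost Pou5f1 steadily, from 468 CPM at 18 h to 39 ± 1.75 at 36 h and 9.55 ± 0.415 at 48 h. Sox1 in RA rose from 4.68 ± 1.2 CPM at 12 h to 162 ± 5.95 at 36 h. Hoxa3 was still rising, from 151 ± 16.9 CPM at 48 h to 431 ± 16.1 at 72 h. In BMP4 cells T passed through a tall peak, 133 ± 2.36 CPM at 36 h (log2 8.25, adjusted p = 1.4e-63) and 132 ± 42.1 at 48 h, and was back at 2.18 ± 0.593 at 72 h. Axin2 in BMP4 cells peaked with it, at 79.5 ± 4.76 CPM at 36 h. Hand1 in BMP4 went from 4.97 ± 0.685 CPM at 12 h to 190 ± 18 at 48 h, and Igf2 from 161 ± 9.3 CPM at 36 h to 1590 ± 274 at 48 h. Nanog in BMP4 dipped to 24.8 ± 3.52 CPM at 3 h, stood at 71 ± 0.36 at 12 h and 75.4 ± 5.35 at 24 h, and was at 53.3 ± 0.124 at 36 h. WAFB cells showed T in 2 waves, 12 CPM at 6 h and, after 0.148 at 24 h, 20.3 ± 4.94 at 36 h. Myh7 in SB reached 90.3 ± 2.72 CPM at 48 h, and Id1 32.4 ± 4.77 at 36 h. Changed genes at 36 h numbered 4121 in RA, 3383 in BMP4, 2986 in SB, 2384 in WA and 1947 in WAFB. In SB at 18 h, 808 genes changed with both libraries, 1397 without replicate 1 and 209 without replicate 2, so that count rests on which library is used. SB at 3 h gave 1480 (665 without replicate 2 and 2111 without replicate 1) and SB at 12 h 1584 (898 to 2045).

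**Figure D3:**
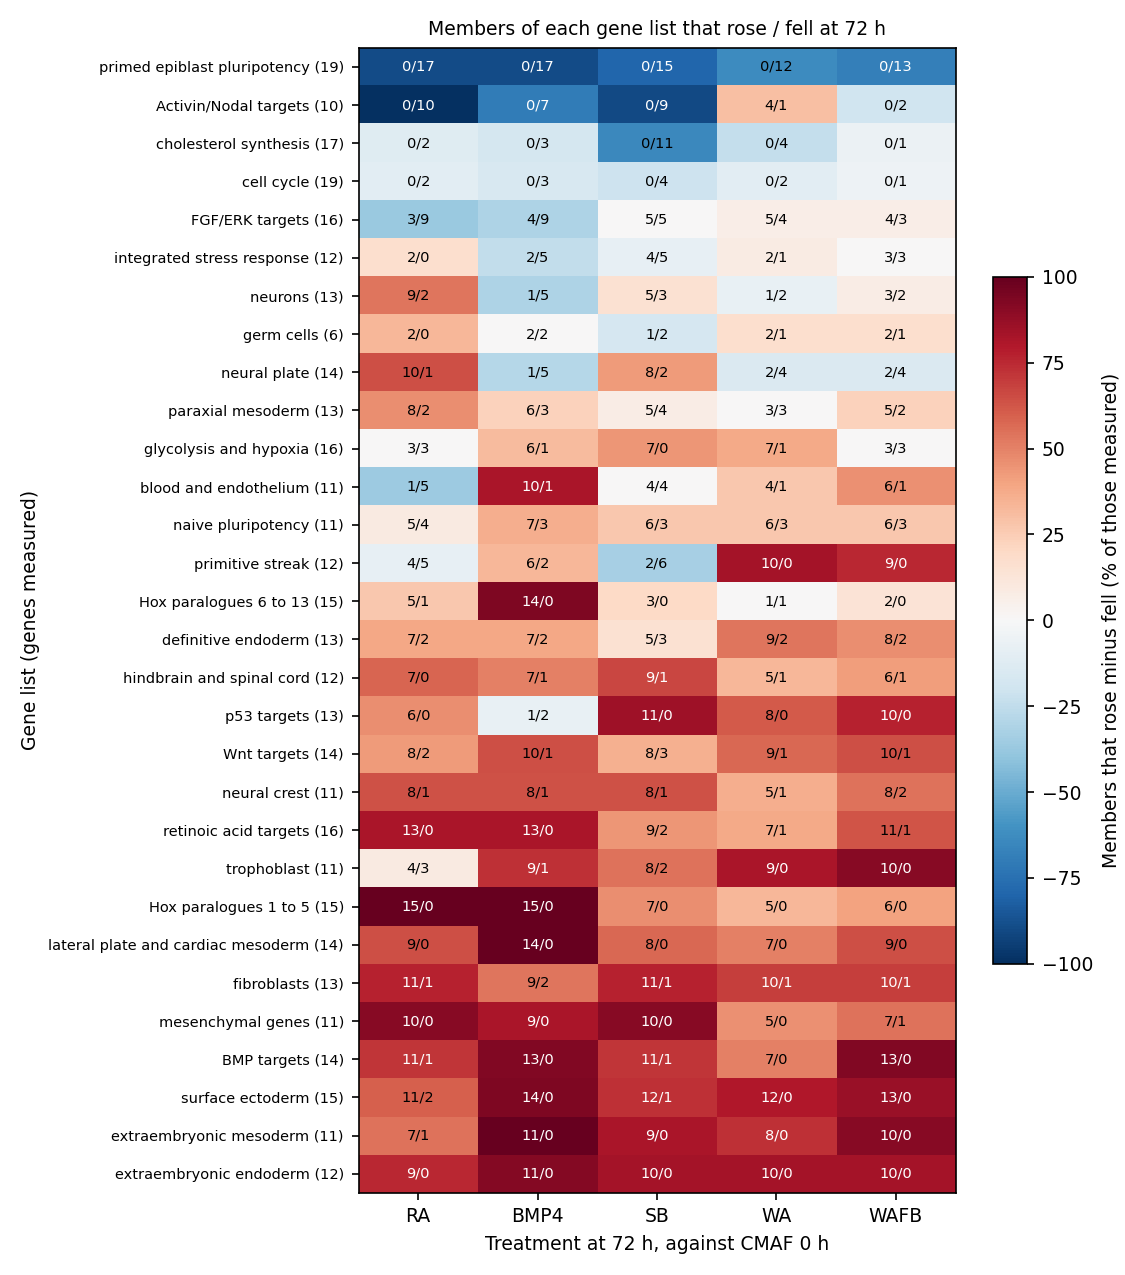
Number of members of each of 30 gene lists that rose / fell against CMAF 0 h at 72 h (columns, treatments; in brackets, genes measured), coloured by the members that rose minus those that fell in percent of genes measured. Primed pluripotency genes fell in every column (12 to 17 of 19), and BMP targets rose in 13 of 14 in BMP4 and WAFB.

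At 72 h primed pluripotency genes fell and extraembryonic endoderm genes rose in all 5 treatments. Other lists follow, some for single treatments only, and likeness between treatments was not tested. Of 19 primed pluripotency genes, 17 fell in RA (adjusted p = 3.78e-18) and BMP4 (adjusted p = 5.24e-14), 15 in SB (adjusted p = 1.87e-11), 12 in WA (adjusted p = 1.77e-06) and 13 in WAFB (adjusted p = 1.56e-07). Of 11 naive pluripotency genes 5 to 7 rose and 3 or 4 fell, with no camera p under 0.05, and of 6 germ cell genes 1 or 2 rose. Extraembryonic endoderm genes rose, from 9 of 12 in RA (10 adjusted over the list alone) to 11 in BMP4, with adjusted p between 2.67e-06 in WAFB and 0.000562 in RA. Extraembryonic mesoderm genes rose in 8 of 11 in WA (adjusted p = 0.000525) and 9 in SB (10 adjusted over the list alone; adjusted p = 0.00024). Mesenchymal genes rose in 10 of 11 in RA (adjusted p = 1.15e-05) and SB (adjusted p = 0.00024), and fibroblast genes in 11 of 13 in both (adjusted p = 0.000305 and 0.000828). Of 13 paraxial mesoderm genes 8 rose and 2 fell in RA (adjusted p = 0.00969). The cell cycle list shifted down without large changes, 1 to 4 of 19 genes past the fold threshold, with adjusted p between 8.16e-06 in SB and 0.00111 in RA. The call held with an estimated correlation in SB and WAFB and was lost in the others (adjusted p = 0.0989 with an estimated correlation in RA, 0.0982 in BMP4 and 0.0723 in WA). Of 12 integrated stress response genes 5 fell and 2 rose in BMP4 (adjusted p = 0.0489; adjusted p = 0.332 with an estimated correlation).

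RA and BMP4 were given in the same base medium, so their difference at 72 h sets the 2 signals against each other. Neural genes stood higher in RA, and surface ectoderm, trophoblast and blood and endothelium genes in BMP4. Higher in RA were the neural RNA Miat (985-fold), Hoxa5 (607-fold), Pou3f2 (252-fold), Sox21 (247-fold), Sox1 (90.2-fold) and Sox2 (19.1-fold), and Dbx1 was at least 1090-fold higher. Hoxaas3, 302-fold higher, overlaps the Hoxa genes and cannot be told from them without strand. Higher in BMP4 were Hand1 (1440-fold), Dkk1 (210-fold), Tbx3 (110-fold), Tfap2a (73.4-fold), Gata4 (42.4-fold) and Id1 (3.81-fold), and Cdx2 was at least 201-fold lower in RA. Of 13 neuronal genes 12 were higher in RA (adjusted p = 2.07e-07) and of 14 neural plate genes 11 (adjusted p = 1.85e-07). All 15 surface ectoderm genes (adjusted p = 1.81e-08), all 11 trophoblast genes (adjusted p = 6.62e-07) and 10 of 11 blood and endothelium genes (adjusted p = 2.19e-05) were lower. Hox paralogues 1 to 5 were higher in RA in 13 of 15 (adjusted p = 7.26e-08), and paralogues 6 to 13 lower in 10 of 15 and higher in 4 (adjusted p = 0.0452; adjusted p = 0.376 with an estimated correlation). In all, 1845 genes were higher and 2587 lower in RA.

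WAFB and WA shared Wnt3a and Activin A on the first day, in different base media and at different Activin A doses. EGTA is given for the first day of WA only. At 24 h 438 genes differed, 205 higher and 233 lower in WAFB. Txnip and the overlapping Gm15441 were both 8.83-fold higher in WAFB, counted without known strand, and Arrdc4 was 7.19-fold higher. Tdh was 11.2-fold lower, Fgf8 4.6-fold and Eomes 3.12-fold, and Foxa2 was at 0.18 CPM (8 counts) against 3.55. Targets of p53 stood higher in WAFB as a set (adjusted p = 7.96e-14), although only 2 of 13, Cdkn1a and Phlda3, passed the fold threshold.

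After 2 more days, 1550 genes differed at 72 h, 915 higher and 635 lower in WAFB. WAFB had FGF2 and then BMP4 on these days, with Activin A at 25 and then 10 ng/ml. WA had Activin A at 100 ng/ml with 0.2% FBS. The comparison joins these differences, so none of the changes can be credited to FGF2 or BMP4 alone. The largest rises included Hand1 at 93.1-fold, Tbx3 63.6-fold, Msx1 30.9-fold, Gata2 20.4-fold and Id1 16.1-fold (204 against 12.9 CPM). T was 4.68-fold higher in WAFB. Lower were the Nodal-pathway genes Lefty1 (29.4-fold), Lefty2 (7.88-fold) and Cer1 (0.559 against 3.69 ± 3.77 CPM, 0.574 to 10.8 in the WA libraries), Foxa2 (3.06-fold) and Nanog (2.51-fold). Of 14 BMP targets 12 were higher (adjusted p = 2.1e-16), of 14 Wnt targets 8 (9 adjusted over the list alone; adjusted p = 3.74e-06), and 7 of 10 Activin and Nodal targets were lower (adjusted p = 0.0667). Glycolysis and hypoxia genes were lower, 6 of 16 (adjusted p = 8.86e-13), with Pdk1 4.38-fold and Bnip3 4.33-fold. Sox17, Axin2 and Pou5f1 did not differ past the thresholds.

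SB and RA were compared at 72 h because neither medium had Wnt3a, Activin A or BMP4 added. SB cells were in serum-free medium and RA cells in conditioned medium. The comparison therefore joins SB431542 and retinoic acid with the base medium. SB carried surface ectoderm and trophoblast genes that stood lower in RA. Grhl2 was 29.7-fold higher in SB, Cdh1 14.3-fold and Krt8 11.6-fold, and 13 of 15 surface ectoderm genes (14 adjusted over the list alone; adjusted p = 2.26e-05) and 9 of 11 trophoblast genes (adjusted p = 0.00486) were higher. RA carried the Hox and neural genes: Hoxa3 was 830-fold lower in SB, Unc5a 554-fold, Hoxb4 272-fold, Cyp26a1 195-fold, Pou3f2 55.3-fold, Sox1 8.45-fold and Zeb1 6.18-fold. All 15 Hox genes of paralogues 1 to 5 were lower in SB (adjusted p = 1.67e-15), as were 10 of 13 neuronal genes (adjusted p = 0.000189) and 7 of 14 neural plate genes, with 3 higher (adjusted p = 0.00486). Glycolysis and hypoxia genes were higher in 11 of 16 (adjusted p = 8.31e-05; adjusted p = 0.0932 with an estimated correlation). Sox2, Nanog and Pou5f1 did not pass the thresholds. In all, 2227 genes were higher and 2260 lower in SB.

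Many genes were shared between treatments at 72 h. RA and BMP4 shared 2169 rising genes where independent lists would share 794, and a median of 2040 (2005 to 2079 over 20 splits) with the 6 controls split between the treatments. Falling genes numbered 1230 (306 for independent lists, 1175 with split controls). WA and WAFB shared 2437 rising genes (596, 2241.5) and 989 falling (125, 931), and SB and RA 2042 rising (709, 1908.5) and 1277 falling (318, 1214). All 5 treatments shared 1202 rising genes (6.4, 1084) and 461 falling (0.374, 436.5). Unchanged groups simulated against the same controls shared 0 genes in each of 20 simulations for all of these. They were drawn at the means of those controls, so they cannot show what chance values of the controls add. The comparisons share their control libraries, and neither the independent lists nor the split controls alone remove that part.

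Some genes moved one way at 6 h and the other way at 72 h, past the thresholds both times and between the times. There were 119 in RA, 88 of them up and then down, 72 in BMP4 (61 up and then down), 80 in SB (46), 38 in WA (15) and 41 in WAFB (14). In SB, Axin2 was 2.25-fold lower at 6 h and 13.8-fold higher at 72 h. In RA, Nr0b1, a gene of the naive state, rose by 4.38 on the log2 scale at 6 h and fell by 1.47 at 72 h. Col1a2 in WA fell by 1.07 at 6 h and rose by 4.58 at 72 h.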

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

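The counts over other splits of the libraries, the tests for SB 18 h replicate 1, the tests of sampling between 3 and 6 h and before 3 h, and the tests of shared controls and of handling for the common 6 h response were chosen after the result was seen.

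SB 18 h replicate 1 lay near CMAF: Lefty1 was at 195 CPM in it and at 0 in replicate 2, against 140 ± 9.52 CPM (SD, n = 6) in CMAF, and Nanog was at 54.4 against 7.48 CPM. Projected on the mean SB change of 12 and 24 h over 849 genes, it had a slope of 0.0873, where replicate 2 had 0.955, the SB libraries of 12 and 24 h 0.802 to 1.23 and the CMAF libraries -0.0145 to 0.0113. A swap with a CMAF library is argued against, since the highest CMAF slope was 0.0113, while a wrong label or a culture that did not take up the inhibitor may explain the slope of 0.0873. A mixture with a small share of SB-treated material cannot be told apart from these: the slope lay under the bound of 0.1 first set against a mixture, but that bound was too high, since the slope also lay above every CMAF library. No biological explanation was tested.

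BMP4 6 h replicate 6 stood between CMAF and the other BMP4 6 h libraries: over 263 genes its median share of the 6 h change was 0.421 (0.416 in 211 that rose and 0.463 in 52 that fell), where the other 5 libraries had 0.982 to 1.02. Id1 was at 76.4 CPM against 187 to 204 in the others, Pou5f1 at 1520 against 1280 to 1340, and Nanog at 36.3 against 22 to 27.3, and its distance from the rest of its group was 0.214 against 0.149 to 0.172 (root mean square log2). Sampling between 3 and 6 h is argued against: 124 genes past 0.8 of the change by 3 h stood at a median share of 0.433 (interquartile range 0.367 to 0.516), and genes picked that way in one 3 h library were at 1.01 (0.813 to 1.33) in the other. Sampling before 3 h stays open: the 5 late genes had a median share of 0.377, past the limit of 0.35 set against earlier sampling, but their range of 0.325 to 0.506 spans it, and genes late in one 3 h library stood 0.0972 above their share in the other (interquartile range -0.183 to 0.324). A mixture with CMAF material, for which early genes stood 0.0553 above late ones, within the limit of 0.15 set beforehand, cannot be told apart from it because the late genes are so few, and no biological explanation was tested.

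At 6 h, 148 genes rose in all 5 treatments, where independent lists would share 0.0122, 5 genes fell in all 5, and 93 of the 148 rose in all 5 at 24 h and 108 at 72 h. They included, chosen after their values were seen, the metallothionein gene Mt2 (log2 4.19 to 5.39), the annexin gene Anxa2 (3.13 to 5.59) and the keratin gene Krt19 (2.82 to 3.83). Chance values of the shared controls are argued against as the whole cause. With the controls split, a median of 100.5 genes (97 to 111 over 20 splits) still rose in all 5. In 20 simulations 0 genes rose in all 5 unchanged groups, but these were drawn at the control means and so cannot test it. A change of the base medium is argued against as the whole cause by the definition of the 148 genes. Each of them also rose in RA and BMP4, which stayed in conditioned medium. They made up 62.4% of the 237 genes that rose in SB, WA and WAFB, a share of the same genes and so no separate test. Handling or renewal of the medium may be the source, and cannot be told apart from a response to leaving CMAF, because 0 libraries came from cells given fresh CMAF.

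Of 145 sets of library values tested with Dixon's test, 18 held a library far from the others, where chance gives about 1 in 20 sets, or 7.2; 4 of the 18 are the BMP4 6 h values above. WAFB 6 h replicate 4 was 0.601 from the rest of its group (0.252 to 0.274 in the others), with 20.2% of counts in its 10 highest genes (3.51 to 3.93%), Pou5f1 at 2590 CPM (1590 to 1830) and Axin2 at 15.1 (10.1 to 11.8). WA 72 h replicate 4 was 0.587 from its group (0.239 to 0.277), with 16500 genes detected (17000 to 17200), Nanog at 30.6 CPM (41.4 to 47), T at 9.9 (14 to 16.3), Id1 at 22.2 (9.86 to 12.4) and Lefty2 at 240 (162 to 187). WA 24 h replicate 2 had 17400 genes detected (16000 to 16500) and Nanog at 135 CPM (160 to 170). Nanog was at 86.1 CPM in WAFB 24 h replicate 4 (103 to 108), and Lefty2 at 35 in WAFB 72 h replicate 1 (18.2 to 23.5).

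For several list genes the change against CMAF had opposite signs at 6 and 72 h, and the difference, 72 h minus 6 h in log2, was itself tested. In RA it was -6.22 for Hoxd13, -5.85 for Nr0b1 and -4.64 for Gcm1. In BMP4 it was -3.57 for Chac1 and -2.54 for Trib3. In SB it was -5.79 for Nr0b1, 4.95 for Axin2 and -2.53 for Tubb3. In WA it was 5.64 for Col1a2, 3.67 for Klf4 and -2.84 for Dcn, and in WAFB 5.64 for Col1a2, -3.54 for Dcn and 3.51 for Atf3.

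The single libraries of RA at 3 h and WA at 48 h entered no comparison and had values outside the CMAF range. Only values above the range and of at least 5 CPM were flagged. RA at 3 h had Cyp26a1 at 154 CPM (0 to 0.183 in CMAF), Sox2 at 172 (86.7 to 97.3) and Pou5f1 at 1910 (1600 to 1740). WA at 48 h had Nanog at 126 CPM (52.6 to 68.5 in CMAF) and Axin2 at 12.5 (2.78 to 4.39). Other genes lay below the range, and those given here were chosen after their values were seen. In RA at 3 h Nanog was at 12.6 CPM and Lefty2 at 6.06 (21.2 to 28.8 in CMAF). In WA at 48 h Pou5f1 was at 756 CPM, Sox2 at 12.2 and Lefty2 at 17.

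In each of 19 comparisons fitted to its 2 groups alone, 60 of the 462 splits of the libraries were drawn, the real one among them. Only the real one gave as many changed genes. A chance split of these libraries is thus argued against for each, at no finer than 1 in 60, and the splits not drawn were not examined. The labels do not say whether the libraries of a group came from separate cultures, and if they did not, chance differences between cultures are not covered. The highest other split gave 0 genes for RA, SB and WA at 6 h (736, 682 and 1169 in the real split), BMP4 and SB at 24 h (1794 and 1416), RA, BMP4 and SB at 72 h (4034, 4965 and 4742), RA against BMP4 at 72 h (3459) and WAFB against WA at 72 h (983), and 2 for WAFB against WA at 24 h (209). It gave 303 for BMP4 at 6 h (430), 137 for WAFB at 6 h (840), 564 for RA (2288), 934 for WA (2272) and 994 for WAFB (2202) at 24 h, and 901 for WA (3363) and 1355 for WAFB (3067) at 72 h, each in a split that exchanged 1 library. For SB against RA at 72 h it gave 2676 (3641), in a split that exchanged 5 libraries and so was near the mirror of the real one.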

How the results depend on the processing

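The alternatives with the partial library and without the 4 libraries in doubt (SB 18 h replicate 1, BMP4 6 h replicate 6, WAFB 6 h replicate 4 and WA 72 h replicate 4) were chosen after the data were seen. The 201 gene changes named kept their direction in all 3562 recomputed values, and 3560 kept their side of the adjusted p threshold. The exceptions were Axin2 in SB at 6 h with replicates 1 and 2 only (log2 -1.14, adjusted p = 0.074, 2.7e-06 to 0.00027 in its other alternatives) and Col1a2 in WA at 6 h with replicates 3 to 6 only (log2 -0.94, adjusted p = 0.07, 0.0003 to 0.03 in the others). The counts against CMAF at 6, 24 and 72 h were 0.981 to 0.995 times the value given with DESeq2, 0.993 to 1.01 with RLE scaling, 1.04 to 1.11 with no filter on low counts, 0.784 to 0.954 with replicates 3 to 6 only, 0.919 to 1.14 without 1 replicate number in all treated groups of 6 and 0.947 to 1 without 1 CMAF library. DESeq2 shared 94.1 to 98.2% of the genes changed against CMAF and 84.5% of those between WAFB and WA at 24 h.

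With only the groups compared, fewer genes passed the filter (12389 to 13740), and the counts were 736 in RA, 430 in BMP4, 682 in SB, 1169 in WA and 840 in WAFB at 6 h, 1794 in BMP4 and 1416 in SB at 24 h, and 209 and 983 between WAFB and WA at 24 and 72 h. In RA at 6 h, 581 of the 1318 changed genes were not tested, and 734 of the other 737 stayed changed. Replicates 1 and 2 only, with fewer samples, gave 856 in RA and 1041 in WAFB at 6 h and 233 between WAFB and WA at 24 h. Leaving out 1 of the 2 libraries in all groups of 2, the lone one assumed to vary like the other groups, gave 665 (without replicate 2) to 2111 in SB at 3 h, 898 (without replicate 2) to 2045 at 12 h, and 209 (without replicate 2) to 1397 (without replicate 1) at 18 h. Without the 4 libraries in doubt SB at 18 h gave 1434. The partial library gave 1.07 times the count of RA at 72 h against CMAF. Of the list tests, 229 had an adjusted p under 0.05 with the preset correlation and 123 with an estimated one. The runs differed only in this correlation, so many of the list results rest on the preset value. The residuals of same-numbered libraries correlated by -0.0025 on average (-0.19 to 0.3), and 9 of 95 libraries correlated best with their own number. A replicate block gave 0.998 to 1.01 times the counts at 6, 24 and 72 h and 0.991 times the number of lists. In simulation at the depth of these libraries, the changed genes were all well above 0 counts in CMAF. Of 2-fold changes, the limit of a call, 44% were called with 5 against 6 libraries and 36% with 2 against 6. Of 4-fold ones 100% were called with either. Genes near 0 counts in CMAF are not covered by these shares.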

Other observations

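The values in this part were picked after they were seen, no explanation was tested for them, and the differences between times were not tested. In SB cells Cyp26a1, which encodes an enzyme that breaks down retinoic acid, was high for a time, at 1.05 ± 0.469 CPM (SD, n = 6) at 6 h, 13.8 ± 0.144 (n = 2) at 12 h, 14.3 ± 4.41 (n = 6) at 24 h and 0.351 ± 0.275 (n = 6) at 72 h. Id1 in SB cells was at 8.82 ± 2.28 CPM (n = 6) at 24 h and 58.2 ± 2.52 (n = 2) at 48 h. Nanog in BMP4 cells was at 24.8 ± 3.52 CPM (n = 2) at 3 h, 77.7 ± 0.295 (n = 2) at 18 h and 3.32 ± 0.902 (n = 6) at 72 h. In RA cells Sfrp5, which encodes a secreted Wnt inhibitor, was at 0.372 ± 0.152 CPM (n = 6) at 6 h, 88.4 ± 6.15 (n = 2) at 36 h and 2.88 ± 0.811 (n = 5) at 72 h, where Axin2 was at 41.9 ± 1.84.

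WA and WAFB cells had 2384 and 1947 changed genes at 36 h (n = 2) and 3365 and 3302 at 24 h (n = 6), so the counts rest on different numbers of libraries. Pou5f1 was at 1220 ± 7.22 and 1460 ± 90.8 CPM at 36 h and at 789 ± 60.3 and 823 ± 38 at 24 h. After 24 h Wnt3a and EGTA were left out of the WA medium and 0.2% FBS was added. In the WAFB medium FGF2 was added and Activin A went from 50 to 25 ng/ml.

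SB 3 h, SB 12 h and RA 12 h replicate 2 had 6.2%, 3.21% and 6.15% of 8680 genes more than 2-fold lower than in the other library of the group, and 0.0115%, 0% and 0.426% more than 2-fold higher. These differences correlated by 0.78 to 0.88 between the 3 groups across genes, which are not independent replicates. Those of WAFB 6 h replicate 4 correlated with them by 0.65, 0.59 and 0.73, those of WA 72 h replicate 4 by 0.25, 0.25 and 0.57, and the latter 2 with each other by 0.43. RA at 12 h had 1533 changed genes, 2291 without replicate 1 and 1167 without replicate 2. In WAFB 6 h replicate 4 the shares against the rest of its group were 3.97% lower and 1.95% higher, and in WA 72 h replicate 4 6.22% and 0.668%.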
